A study of Mus musculus with 13 samples.

How the data were processed

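The series holds 13 samples of C2C12 cells, a mouse myoblast line that grows as single cells and fuses into myotubes when serum is lowered. By the labels, 4 are RNA-seq libraries and 9 are ChIP-seq libraries. The work used 2 libraries, RNA-seq of myoblasts labelled siNC and siLinc-Yy1, with 1 library per condition. The RNA-seq libraries labelled GM and DM were not analysed here, nor were the ChIP-seq libraries for Ezh2, Eed, H3K27me3, Yy1 and IgG from cells labelled vector or Linc-Yy1.

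Both libraries came in 1 gene-level Cuffdiff table, present as 2 identical copies, of which 1 was read. The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) that the authors estimated per gene and condition, per the file headers. The p-value and q-value columns hold the test the authors ran on the same pair of libraries, per the file headers. The other deposited column used was the authors' log2 fold change, which served only to check the direction. The table's header replaces the usual condition columns with siNC and siLinc-Yy1, and the first and second FPKM columns were taken in that order, which is Cuffdiff's own. The submitters' processing notes name TopHat2 2.0.4, Cufflinks 2.1.1, Cuffdiff 2.0.4, MACS2 1.4.2 and the mouse build mm9. The scaling between libraries, the gene annotation, the use of strand and the treatment of duplicate reads are not given in the sources used here. RNA was selected for poly(A), per the labels.

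The table has 23236 rows, of which 88 name several genes and 4176 share a locus with another row. For such rows, and for near-identical copies such as histone genes, the authors' estimate had to divide reads between genes, so single values are uncertain. Status was OK in 14366 rows, NOTEST in 8672, LOWDATA in 148, FAIL in 49 and HIDATA in 1. In the 49 FAIL rows the deposited fold change is 0 whatever the FPKM values. In all other rows with values above 0 the deposited fold change and the ratio of the FPKM columns differed by at most 2.4e-05 on the log2 scale. An exact 0 can be a failed estimate, since the ribosomal RNA row Rn45s, with status HIDATA, stands at 1004 FPKM in siNC and is listed at 0 in siLinc-Yy1.

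The change of each gene was computed as log2 of (FPKM + 1) in siLinc-Yy1 over (FPKM + 1) in siNC, which understates changes of low genes. A gene was counted as higher or lower when this value was at least 1 or at most -1, among the 11792 rows with a mean FPKM of at least 1. With 1 library per condition there is no replicate check, and genes are not replicates, so no p-value, standard deviation or standard error was computed. Every difference describes a pair of libraries and not the conditions they stand for. Calls and q-values quoted from the authors' deposited table carry the same limit.

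The main settings, 29 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The median of each list with at least 5 members past the filter was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below the 2.5th or above the 97.5th percentile. Of 26 lists placed this way, about 1.3 are expected to stand apart by chance if genes vary independently of each other. Genes of a list can vary together between any pair of libraries, so the number apart is no test against chance. The named genes were the Linc-Yy1 row, Yy1 and rows within 100 kb of Yy1, then Ezh2, Eed and Suz12. They also took in the 12 highest and 12 lowest single-gene rows with status OK and a mean FPKM of at least 5, and up to 4 members per list with the largest absolute change. Some genes that this rule takes are not reported here. Other genes in the text were chosen after their values were seen.

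Depth was read from single-exon odorant, pheromone, taste and trace amine receptor rows, whose FPKM at low levels steps by 1 fragment. If no further scaling was applied between the libraries, these steps gave about 65.9 M fragments for siNC and 47.5 M for siLinc-Yy1. Within a tolerance of 0.02 fragments, 58.4% of 627 such rows in siNC and 49.3% of 527 in siLinc-Yy1 were whole multiples, so no count test was run. At 1 fragment, the FPKM in siLinc-Yy1 was 1.39 times that in siNC. Counts derived this way are upper limits for a gene whose transcript is shorter than its locus. Intervals from them, exact binomial ones, cover counting error only.

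The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a mean FPKM of at least 5, rescaling to equal summed FPKM, centring on the median and a fold of 1.5. They also included the calls in the authors' deposited table, rows with status OK alone and random lists without matching. After the data were seen, 2 more were added: subtraction of a running median over 301 rows ordered by mean FPKM, and removal of histone and small structured RNA genes. The size rule and the list method were tested on simulated data of 11800 genes. All of 200 genes changed 4-fold were recovered with 0 others, 3% of 200 unchanged lists stood apart, and 100% of 50 lists of 20 genes shifted by 0.5 stood apart. The changed genes were drawn from those of at least 5 FPKM. Simulated noise was independent between genes and of equal log2 spread at all levels, with no trend with abundance. The simulation thus checks that the rules run as designed, not how they perform on these libraries. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are those of the table on mm9, with starts counted from 1.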

Results

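RNA-seq profiles of C2C12 myoblasts in growth were compared between a library labelled siNC and a library labelled siLinc-Yy1. By the usual reading of such names, these are a control siRNA and an siRNA against Linc-Yy1, a long intergenic noncoding RNA named for its neighbour Yy1. The comparison asks which transcripts differ in myoblasts when Linc-Yy1 is targeted. Each condition has 1 library, so no difference below has a replicate check, and all values describe these libraries. If no further scaling was applied between the libraries, which was not tested, the steps of low FPKM values give about 65.9 M (siNC) and 47.5 M (siLinc-Yy1) fragments. A mean of at least 1 FPKM was reached by 11792 of 23236 rows.

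The targeted RNA itself was scarce. The row lincYy1, on chromosome 12 from 110028244 to 110029417 (mm9), just before the Yy1 gene, measured 0.360 FPKM in siNC and 0.227 FPKM in siLinc-Yy1. These values correspond to at most 26 and 12 fragments. The ratio of 0.629 had a counting interval (95%) of 0.296 to 1.32 at its narrowest, so a fall of the target was not resolved at this depth. In the authors' deposited table its q-value was 0.878. The level of the target therefore neither bears out nor contradicts the label of the siLinc-Yy1 library.

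Yy1, a zinc finger transcription factor on chromosome 12 from 110031521 to 110054842, measured 28.6 FPKM in siNC and 30.9 FPKM in siLinc-Yy1. Its other neighbours within 100 kb also lay close together in both libraries. Wars, the cytosolic tryptophanyl-tRNA synthetase, measured 43.3 and 52.8 FPKM, and Slc25a29, a mitochondrial carrier, 6.42 and 5.27 FPKM. Evl and Eml1, whose locus in the table also holds Degs2 and Gm16596, stood at 46.6 and 49.6 FPKM and at 35.8 and 34.0 FPKM. Degs2 was at 1.11 and 0.924 FPKM and Gm16596 at 1.21 and 0.894 FPKM. Slc25a47 measured 1.43 FPKM in both libraries, Wdr25 3.06 and 3.55 FPKM, and Mir345 was listed at 0 in both.

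The core subunits of Polycomb repressive complex PRC2, which methylates histone H3 at lysine 27, were expressed at similar levels in both libraries. Ezh2, the methyltransferase, measured 29.7 FPKM in siNC and 25.6 FPKM in siLinc-Yy1. Eed measured 20.4 and 22.5 FPKM, and Suz12 17.2 and 13.8 FPKM. The 11 members of the fixed PRC2 list had a median log2 fold change of -0.088, at the 9.69th percentile of matched random lists, with 5 members higher and 6 lower. Among members of at least 5 FPKM the median turned to 0.053, at the 82.6th percentile. Among the 21 rows of PRC1 proteins and H3K27 demethylases the median was 0.0055, at the 91.3rd percentile. Its named members were Cbx7 (5.17 and 6.80 FPKM), Kdm6b (14.2 and 17.9 FPKM) and Rybp (9.75 and 7.81 FPKM). The authors' deposited table called no member of either list.

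Across all genes the libraries were close. The log2 fold change of siLinc-Yy1 over siNC, with 1 FPKM added to each value, had a median of -0.021, and its central 95% ran from -0.38 to 0.71. Of the rows past the filter, 96.2% differed by less than 1.5-fold. At least 2-fold higher in siLinc-Yy1 were 164 genes, and 21 were at least 2-fold lower. Of the 164, 12 were listed at 0 in siNC, and of the 21, 16 were listed at 0 in siLinc-Yy1. A short row can pass the FPKM filter with few fragments, so single small RNA and microRNA rows are uncertain. The authors' deposited table called 76 of the 164 and 2 of the 21. The 164 comprised 36 histone genes, 65 small nucleolar and other small structured RNA genes, 20 microRNA genes and 43 others. Without the histone and small structured RNA genes the counts were 63 and 12. When the libraries were rescaled to equal summed FPKM, the median gene shifted to -0.30 and the counts became 89 and 38. Among genes at least 2-fold changed, the share that were higher thus went from 88.6% to 70.1%. Unless stated otherwise, list medians and counts of members higher and lower are at the authors' scaling, and each percentile compares a list with random lists treated in the same way. The authors' deposited table called 233 genes, 186 of them higher and 47 lower in siLinc-Yy1. These calls have no 2-fold bound, and 62 of the 233 had a mean below 1 FPKM.

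The 12 highest named rows included 10 small RNA or microRNA rows, of which 8 share a locus with another gene. Scarna9 and Snord68 were listed at 0 in siNC and stood at 206 and 18.6 FPKM in siLinc-Yy1. Rnu12, an RNA of the minor spliceosome with its own locus on chromosome 15, measured 154 and 875 FPKM. Snord42a (35.8 and 215 FPKM), Snord73a (4.94 and 33.6 FPKM), Snora44 (7.94 and 42.7 FPKM) and Snord66 (14.4 and 65.4 FPKM) were also among them. So were Mir1949 (6.62 and 43.5 FPKM), Mir3064 (7.85 and 43.6 FPKM) and Mir5109 (347 and 1496 FPKM). The remaining rows were Gm20594, on chromosome 6 from 79768025 to 79768358 (227 and 2233 FPKM), and AI506816 (2.95 and 18.2 FPKM). Of these 12 the authors' deposited table called Rnu12, Mir5109, Gm20594 and AI506816, and it called 13 of all 124 small structured RNA rows.

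The 12 lowest named rows held 7 small RNA or microRNA rows and 5 others. Of the 5 others, Ifit3, Ifit1 and Mx2, interferon-induced antiviral genes, stood at 52.8 and 23.8, 32.4 and 18.5, and 9.76 and 4.53 FPKM. I830012O16Rik, on chromosome 19 from 34682447 to 34687891 and beside the Ifit genes, measured 35.2 FPKM in siNC, with a ratio of siLinc-Yy1 over siNC of 0.397. Gzme, a granzyme, measured 19.5 and 10.8 FPKM. The small RNA rows were Snord45b (17.9 FPKM and listed at 0), Mirlet7c-2 (8.66 and 2.39 FPKM), Mir684-2 (7.33 and 2.77 FPKM), Rnu73b (14.6 and 6.34 FPKM), Snord71 (9.44 and 4.76 FPKM), Mir682 (196 and 111 FPKM) and Snord58b (53.8 and 30.4 FPKM). Among the 21 genes at least 2-fold lower, 16 were listed at 0 in siLinc-Yy1. These were Rn45s, with status HIDATA, and otherwise small RNA or microRNA rows. Some of them held the same value in siNC, as rows of few fragments can. Mir27b and Mir3960 were both at 3.77 FPKM, and Snord72 and Snord91a both at 4.14 FPKM. Of the 21, the authors' deposited table called Ifit3 and I830012O16Rik.

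Abundant transcripts were higher in siLinc-Yy1, and the excess grew with the level. The median log2 fold change was -0.11 among 1698 genes of 2 to 5 FPKM and 0.026 among 2735 genes of 20 to 50 FPKM. It was 0.46 among 175 genes of 200 to 400 FPKM and 1.02 among the 37 genes of at least 800 FPKM, of which 21 were at least 2-fold higher. Eef1a1, a translation elongation factor, measured 967 and 2358 FPKM, Actb 682 and 1325 FPKM, and Gapdh 1213 and 1723 FPKM, 3 genes picked after their values were seen. Because the trend touches every group of abundant genes, each list below was also placed after subtraction of this trend, a step added after the data were seen. Less this trend, Gapdh stood at -0.24, Eef1a1 at 0.54 and Actb at 0.22. At the highest levels the running median reaches over less abundant genes and falls short of the trend. Actb, at a log2 fold change of 0.96, lay below the median of 1.02 of genes of at least 800 FPKM. Values less the trend of the most abundant genes, here and below, therefore tend to be too high.

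**Figure D1:**
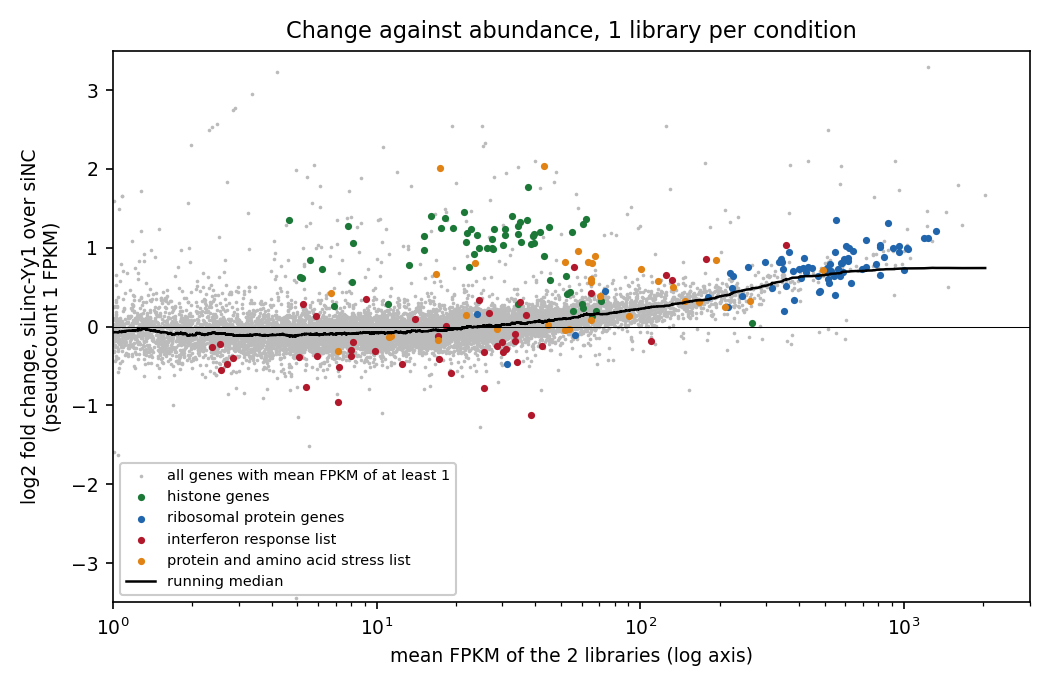
Log2 fold change of siLinc-Yy1 over siNC (vertical axis, with 1 FPKM added) against the mean FPKM of both libraries (horizontal log axis), with 1 point per gene past the filter and 1 library per condition. The black running median rises with abundance, most green histone genes lie above it, and most red interferon genes lie below it; 4 genes beyond a log2 fold change of 3.5 in size are not drawn.

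Of 26 fixed lists with at least 5 measured members, 10 stood apart from matched random lists, and 8 of these still did after the trend was subtracted.

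Interferon response genes were lower in siLinc-Yy1. All 45 list members were measured, 30 lower and 15 higher, and the median of -0.24 lay below every matched random list, also after the trend was subtracted (-0.22). Besides Ifit3, Mx2 and Ifit1, the lower members included Parp14 (7.07 and 3.76 FPKM) and Usp18, which removes Isg15 from proteins (23.2 and 15.0 FPKM). Members that did not follow were B2m, the light chain of MHC class I (234 and 481 FPKM), and Bst2, the antiviral protein tetherin (127 and 229 FPKM). The chemokine Ccl5 (41.5 and 70.8 FPKM) was likewise higher. The authors' deposited table called 5 members lower (Ifit3, Mx2, Ifit1, Parp14, Usp18) and 3 higher (B2m, Bst2, Ccl5). Less the trend, B2m stood at 0.44 and Bst2 at 0.51. Parp14, Usp18 and Ccl5 were picked after their values were seen.

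Genes of the unfolded protein and amino acid stress list were higher in siLinc-Yy1, with 26 of 33 measured members above 0. The median was 0.42, above every matched random list, and 0.21 after the trend was subtracted, again above every random list. Trib3, a pseudokinase induced by the factors ATF4 and CHOP (chromosome 2, 152163161 to 152169796), measured 6.29 and 28.4 FPKM, a ratio of 4.51. Chac1, which degrades glutathione (chromosome 2, 119176978 to 119180062), measured 16.3 and 70.2 FPKM, a ratio of 4.31. Asns, asparagine synthetase, measured 39.1 and 76.8 FPKM, and Slc7a5, a large neutral amino acid transporter, 46.7 and 87.8 FPKM. The authors' deposited table called these 4 and Psph, Mthfd2, Herpud1 and Sesn2 higher, and no member lower. The members did not move together. A division made after the values were seen gave a median less the trend of 0.52 for 17 genes of amino acid supply and the ATF4 and CHOP response. For 16 genes of chaperones and protein folding it was -0.063, and the endoplasmic reticulum chaperone Hspa5 measured 191 and 227 FPKM (-0.15 less the trend).

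Ribosomal protein genes had a median of 0.74, above every matched random list, with 71 of 73 members higher and 11 at least 2-fold higher. After the trend was subtracted the median was 0.12, still above every random list. Before this subtraction, matched random lists had a median of 0.39, as the highest matching bin also takes in less abundant genes. The 83 genes of 400 to 800 FPKM, ribosomal ones among them, had a median of 0.74, like the list. Standing above the random lists therefore does not show an excess over genes of the same level. Rps28 measured 498 and 1240 FPKM, Rps15 796 and 1846 FPKM and Rpl35 749 and 1639 FPKM. The authors' deposited table called 10 members higher. Less the trend, Rps28 stood at 0.59, Rps15 at 0.47 and Rpl35 at 0.39.

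Immediate early genes, which serum and growth factors induce within minutes, had a median of 0.18, with 27 of 30 members higher. It lay above every random list, although under rescaling to equal totals, which lowers all genes, it was -0.10. Ier2 measured 48.2 and 75.2 FPKM, Myc 31.8 and 48.3 FPKM, Ier3 61.7 and 88.3 FPKM and Egr1 69.8 and 98.2 FPKM, and the authors' deposited table called Ier2. NF-kB and cytokine genes had a median of 0.17 at the 99.99th percentile, with 15 of 18 members higher, and -0.10 under rescaling to equal totals. The chemokines Cxcl1 (47.5 and 69.6 FPKM) and Cxcl5 (37.7 and 50.4 FPKM), the acute phase gene Saa3 (6.34 and 8.97 FPKM) and Bcl3 (11.1 and 14.4 FPKM) moved most, and the authors' deposited table called none of the list. Glycolysis and hypoxia genes had a median of 0.25 at the 99.2nd percentile, with 26 of 28 higher, and -0.066 under rescaling to equal totals. Pkm2 measured 618 and 1204 FPKM, Tpi1 373 and 658 FPKM, Aldoa 485 and 829 FPKM and Ldha 433 and 693 FPKM, and the list was no longer apart among genes of at least 5 FPKM (93.1st percentile). Less the trend, the list median was 0.12, with Pkm2 at 0.23, Tpi1 at 0.16, Aldoa at 0.065 and Ldha at -0.00013.

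Cell cycle genes lay slightly below random lists matched on expression, though not below unmatched ones (32.3rd percentile for S phase, 73.2nd for G2 and M phase). The 40 S phase genes had a median of -0.037 at the 1.26th percentile, with 25 lower and 15 higher. After the trend was subtracted it was -0.13, below every random list, whereas among genes of at least 5 FPKM it was not apart (3.18th percentile). Gins3 (11.1 and 7.73 FPKM), E2f2 (10.8 and 8.05 FPKM), Rfc4 (13.0 and 9.96 FPKM) and Gins1 (16.8 and 13.0 FPKM), which serve DNA replication, changed most. The 49 G2 and M phase genes had a median of -0.0011, against 0.095 for matched random lists, and lay at the 0.01st percentile; centring on the median moved it to 0.020. Ube2c measured 127 and 187 FPKM, Pttg1 108 and 137 FPKM, Bub1 17.0 and 13.3 FPKM and Kif20b 14.1 and 11.1 FPKM. The authors' deposited table called no gene of these 2 lists.

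Muscle genes were mixed. The 17 measured myogenic regulators had a median of -0.056 at the 4.02nd percentile, with 11 lower and 6 higher, and were not apart. Under rescaling to equal totals they were (-0.36, 2.28th percentile). Msc (3.92 and 2.63 FPKM) and Tmem8c, which drives myoblast fusion (11.4 and 9.08 FPKM), were lower, while Itga7 (117 and 139 FPKM, -0.016 less the trend) and Mef2d (35.4 and 42.2 FPKM) were higher. The determination factor Myod1 measured 62.5 and 67.0 FPKM and the differentiation factor Myog 22.8 and 19.4 FPKM, both named after their values were seen. The 48 measured sarcomere and contraction genes had a median of 0.042 at the 98.3rd percentile, with 26 higher and 22 lower, and -0.16 under rescaling to equal totals. The list was not apart after the trend was subtracted (78.6th percentile). Tcap, a Z-disc protein (1.87 and 4.70 FPKM), Ckm, muscle creatine kinase (14.5 and 24.9 FPKM), Tnnt3 (31.9 and 52.3 FPKM) and Myh4, a fast adult myosin heavy chain (6.86 and 11.1 FPKM), were higher. Myh3, the embryonic myosin heavy chain, was lower (3.08 and 1.85 FPKM), named after its value was seen. The authors' deposited table called Tcap, Ckm, Myh4 and Mybpc2 higher and Myh3 lower.

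**Figure D2:**
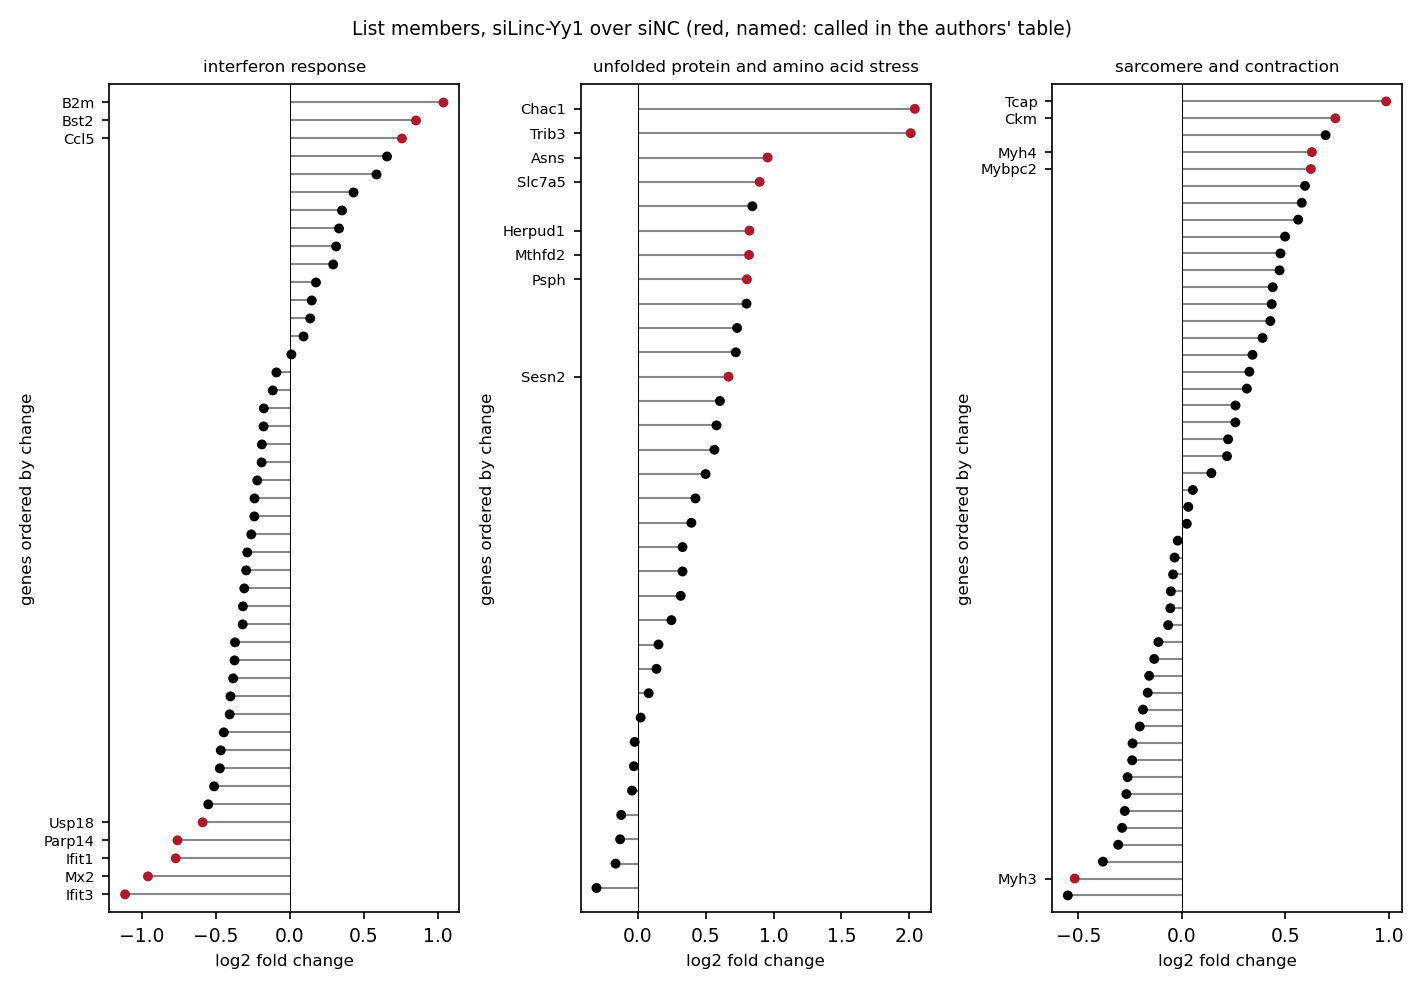
Log2 fold change of siLinc-Yy1 over siNC (horizontal axis, with 1 FPKM added) for each measured member of 3 fixed lists, 1 point per gene and 1 library per condition; red points with gene names are genes called in the authors' deposited table. Of the 45 interferon genes 30 lie below 0, of the 33 stress genes 26 lie above 0, and the 48 sarcomere genes lie on both sides.

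Cholesterol and SREBP genes had a median of 0.13 at the 97.9th percentile and were not apart after the trend was subtracted (92.0th percentile); rescaling to equal totals turned the median to -0.18. Scd2 (189 and 271 FPKM), Scd1 (112 and 155 FPKM), Fdps (160 and 214 FPKM) and Fads2 (100.3 and 123 FPKM) changed most. Oxidative phosphorylation genes had a median of 0.26 at the 22.3rd percentile and were not apart. After the trend was subtracted they lay below every random list, at -0.074, and against random lists without matching on expression they lay above every one. Cox5b measured 271 and 426 FPKM, Cox6a1 269 and 423 FPKM, Atp5b 381 and 564 FPKM and Cox8a 188 and 275 FPKM, or 0.068, 0.075, -0.078 and 0.10 less the trend. The p53 target list had a median of 0.075 at the 96.1st percentile, and at the 98.3rd after the trend was subtracted. Of its 24 measured members 13 were higher and 11 lower, and Sesn2 is also a member of the stress list. Gadd45a (22.1 and 39.1 FPKM), Sesn2 (12.8 and 20.9 FPKM) and Gdf15 (52.4 and 82.8 FPKM) were called higher in the authors' deposited table, and Cdkn1a measured 158 and 224 FPKM.

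The other lists did not stand apart at the main settings. Among genes of at least 5 FPKM, IGF and insulin signalling (0.23, 98.6th percentile) and the Wnt and BMP pathway (0.077, 98.9th percentile) did. Against random lists without matching, heat shock (99.9th percentile) and extracellular matrix genes, above every list, did. Heat shock genes had a median of 0.15 (25.6th percentile) and went both ways, with Hsp90ab1 at 587 and 1155 FPKM, Hspb1 at 375 and 674 FPKM and Hspa8 at 562 and 961 FPKM. Less the trend these 3 stood at 0.25, 0.18 and 0.058. The inducible Hspa1b was lower, at 25.7 and 16.3 FPKM, and the authors' deposited table called it and its near-identical neighbour Hspa1a lower. Extracellular matrix genes had a median of 0.16 (96.7th percentile), with Spp1 at 615 and 1446 FPKM, Timp1 at 231 and 397 FPKM, Sparc at 380.0 and 646 FPKM and Fn1 at 348 and 557 FPKM. Less the trend, the list median was 0.022 (83.5th percentile), with Spp1 at 0.49, Timp1 at 0.24, Sparc at 0.11 and Fn1 at 0.035. TGF-beta and YAP targets had a median of 0.0089 (24.3rd percentile), with Acta2 at 270 and 388 FPKM (-0.040 less the trend) and Cnn1 at 4.69 and 3.32 FPKM. The Notch pathway had a median of -0.10 (9.16th percentile), with Heyl at 2.18 and 1.34 FPKM and Hes6 at 23.7 and 18.8 FPKM. IGF and insulin signalling had a median of 0.044 (73.6th percentile), and the Wnt and BMP pathway 0.012, inside the range of random lists, with Igfbp2 at 334 and 461 FPKM (-0.16 less the trend) and Grem1 at 62.2 and 78.4 FPKM. RNA interference machinery had a median of 0.014 (86.2nd percentile), with Eif2c2, which encodes Argonaute 2, at 15.4 and 17.7 FPKM. Imprinted genes had a median of -0.070 (26.2nd percentile), with Dlk1 at 0.658 and 1.96 FPKM, called higher in the authors' deposited table, H19 at 255 and 375 FPKM (0.0084 less the trend) and Mest at 6.58 and 4.16 FPKM.

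Markers of other cell types gave no list that stood apart. Adipocyte markers had a median of 0.0097 (85.3rd percentile), with Pparg at 8.04 and 10.4 FPKM. Osteoblast and chondrocyte markers had a median of -0.11 (31.0th percentile), with Bglap at 5.16 and 2.55 FPKM and Sox9 at 28.0 and 32.5 FPKM. Neuronal and glial markers had a median of 0.099 (20.5th percentile), with Tubb3 at 117 and 152 FPKM. These 3 lists had 5 measured members each. Fewer were measured of the endothelial markers (3, with Egfl7 at 2.26 and 2.02 FPKM), the macrophage and leukocyte markers (2, with Cd14 at 9.90 and 9.16 FPKM) and the epithelial markers (2, with Krt19 at 36.9 and 43.2 FPKM). Those lists were not placed among random lists.

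**Figure D3:**
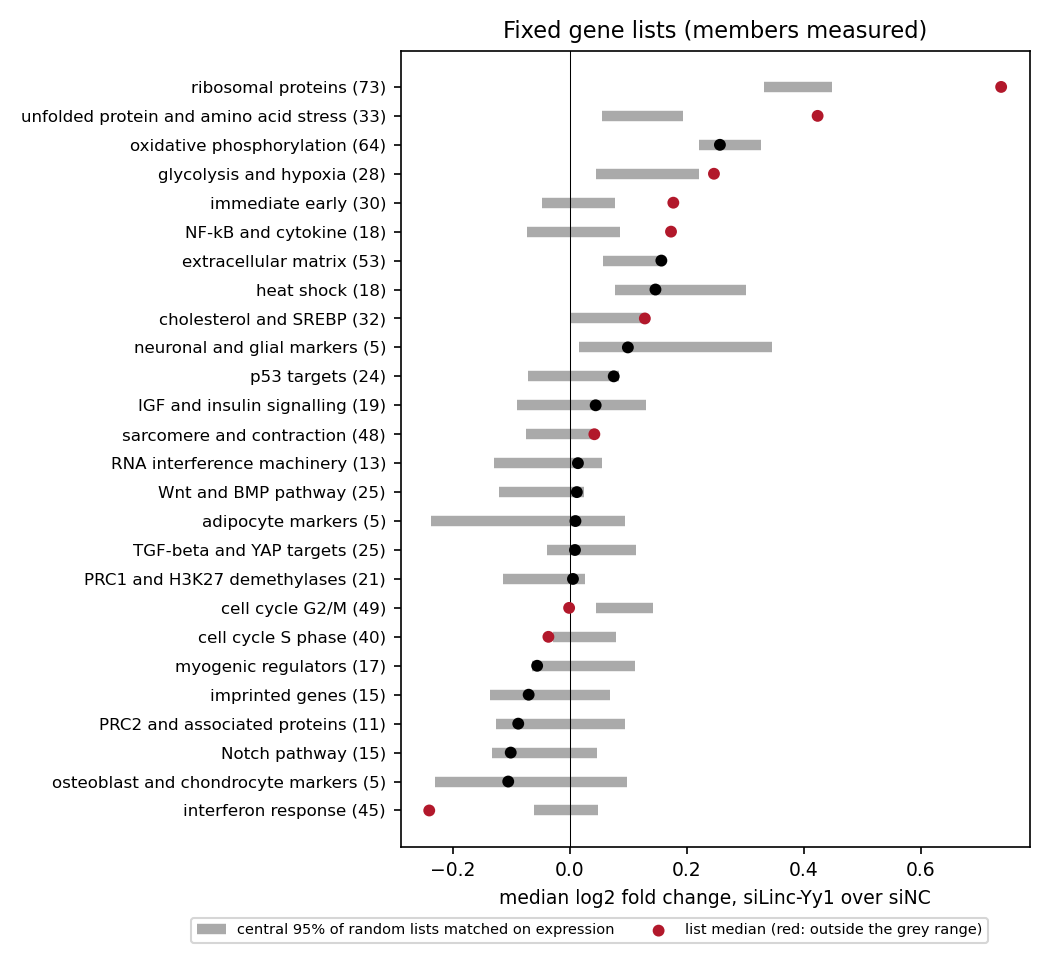
Median log2 fold change of siLinc-Yy1 over siNC (horizontal axis, with 1 FPKM added) for each of 26 fixed lists, with the number of measured members in brackets; grey bars are the central 95% of 10000 random lists matched on expression. The 10 red medians lie outside their bars, from -0.24 for interferon response to 0.74 for ribosomal proteins.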

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

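The subtraction of the trend and the removal of histone and small structured RNA genes were chosen after the data were seen. No paired analysis was possible because each condition has 1 library, and for the same reason no replicate could be left out. Where no reason is stated, the cause was not tested. The 164 higher and 21 lower genes became 109 and 7 with a pseudocount of 5, 387 and 61 at 1.5-fold, and 89 and 38 after rescaling to equal totals. By construction, 63 and 12 were left without histone and small structured RNA genes. Lower genes numbered 39 with no filter, 7 at a mean of at least 5 FPKM and 47 among the calls of the authors' deposited table. Those calls have no 2-fold bound, and 20 of the 47 had a mean below 1 FPKM. Rescaling moved the median gene to -0.30 and so turned the medians of sarcomere (-0.16), NF-kB (-0.10), cholesterol (-0.18), glycolysis (-0.066) and immediate early genes (-0.10), all of which still stood apart on the upper side. Myogenic regulators came to stand apart there (-0.36, 2.28th percentile). Centring moved the G2 and M phase median to 0.020, still at the 0.01st percentile. With a pseudocount of 5, sarcomere genes (0.018) were no longer apart and p53 targets (0.068) were; with no filter, sarcomere genes (0.031) were not. At a mean of at least 5 FPKM, S phase (-0.025), cholesterol (0.13) and glycolysis (0.25) were no longer apart, while IGF (0.23) and Wnt and BMP genes (0.077) were. Random lists without matching leave medians as they are and put the trend into the percentile. There S phase (-0.037, 32.3rd percentile) and G2 and M phase genes (-0.0011, 73.2nd) were not apart, while p53 (0.075), extracellular matrix (0.16), oxidative phosphorylation (0.26) and heat shock (0.15) stood apart on the upper side. Less the trend, sarcomere (0.020) and cholesterol (0.040) were no longer apart, and p53 (0.071) and oxidative phosphorylation (-0.074) were. The interferon, stress and ribosomal lists kept their direction and stood apart under every alternative run on them. For the ribosomal list, none of these compared it with genes of its own level alone. No named gene at least 2-fold changed turned its direction. Depth limits the low genes most, lincYy1 with at most 26 and 12 fragments among them.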

Other observations

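Of the tests in this part, those on duplicate reads, on ribosomal protein transcripts, on less abundant short genes, of the abundance trend on histone genes, on RNA without a poly(A) tail, on the Hist1h2a rows and on the interferon percentile were chosen after the results were seen. Every test on values less the trend also rests on a step added after the data were seen. Such tests include those of interferon genes, of other genes under 1 kb and of genes near Yy1. The genes in the next 2 paragraphs were also chosen after their values were seen. Intervals are 95% ranges of a median over resampled genes, or an exact binomial interval for a share, and do not cover differences between cultures.

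Several genes outside the fixed lists were called in the authors' deposited table, and those named here were not tested as a group. Among those called higher, Aldh1l2, a mitochondrial folate enzyme, measured 6.404 FPKM in siNC and 14.5 FPKM in siLinc-Yy1, and Gpt2, a mitochondrial alanine aminotransferase, 17.4 and 36.1 FPKM. Cth, which makes cysteine, stood at 2.60 and 5.54 FPKM and Pck2 at 20.7 and 37.7 FPKM. The secreted factors Adm2 (0.482 and 2.51 FPKM) and Fgf21 (0.513 and 1.63 FPKM) were called as well, as were Nupr1 (78.2 and 149 FPKM) and Eif4ebp1 (105 and 185 FPKM). The interferon-inducible GTPases Igtp (20.3 and 11.7 FPKM) and Iigp1 (2.94 and 1.54 FPKM) and the RNA sensor Tlr3 (2.14 and 1.22 FPKM) were called lower there. Oas3 (6.13 and 9.57 FPKM) was called higher.

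The 6 Zscan4 rows, near-identical genes known from early embryos and embryonic stem cells, were all lower in siLinc-Yy1, with a summed 2.84 FPKM in siNC and 0.577 FPKM in siLinc-Yy1. The authors' deposited table called each of them, but shared reads make these 6 rows a single observation. Gzmd, a granzyme beside Gzme, measured 3.95 and 1.89 FPKM. Tmem38b, an intracellular cation channel, measured 12.9 and 55.6 FPKM, a ratio of 4.32. Lars2, mitochondrial leucyl-tRNA synthetase, measured 143 and 597 FPKM and was not called in the authors' deposited table. Oprm1 (0.0624 and 2.49 FPKM) and Vsig8 (0.0777 and 2.03 FPKM) were close to absent in siNC.

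Histone genes and small structured RNAs were higher in siLinc-Yy1: 62 of 62 histone genes past the filter (53 after rescaling to equal totals), 36 of them at least 2-fold, and 92 of 104 small structured RNA rows (89 after rescaling), among them Rmrp (163 and 702 FPKM) and Rnu11 (67.1 and 285 FPKM). The histone genes differed among themselves, since less the trend the 12 Hist1h2a rows, none called in the authors' deposited table, had a median of 0.15 (range -0.44 to 0.37) and the other 50 a median of 1.12 (range 0.51 to 1.73). More cells in S phase is argued against, since S phase genes lay -0.061 (-0.21 to -0.013) from matched random lists. So is a general rise of short genes, with -0.017 (-0.11 to 0.072) for 51 other genes under 1 kb. That set left out microRNA rows, of which 20 were at least 2-fold higher and 9 at least 2-fold lower. Lengths as short as theirs were therefore not tested. The abundance trend as the whole cause is argued against too, with 1.03 (0.97 to 1.13) left over all histone genes, though little was left for the Hist1h2a rows. Replication-dependent histone mRNAs and most small structured RNAs carry no poly(A) tail. The histone genes did not rise alike, as the Hist1h2a rows lay -0.97 (-1.08 to -0.78) from the others. That group was picked from these same values, and reads were divided between near-identical copies. The difference therefore does not test whether more RNA without a tail was present. Whether more such RNA may account for the pattern stays open. The 1.11 (1.01 to 1.33) of 92 small structured RNA rows above 0 in both libraries only restates the pattern, and an effect of the siRNA was not tested.

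Abundant transcripts were higher in siLinc-Yy1, 282 of the 294 genes of at least 200 FPKM that are above 0 in both libraries (252 after rescaling to equal totals). Removal of duplicates in the same way from both libraries could hold such genes to at most 1.39-fold, the ratio of the value of 1 fragment. This bound assumes that each gene offers equally many distinct fragments in both libraries, which was not tested. Of these genes, 64.6% (58.9 to 70.1) exceeded it, which argues against such removal only under that assumption. A change of ribosomal protein genes alone is argued against by 0.52 (0.48 to 0.55) for 205 abundant genes of other kinds. So is a fragment length difference that raises all short genes. The 47 less abundant genes under 1 kb, whose transcripts must be short, lay only 0.018 (-0.11 to 0.14) above the median gene. Histone, small structured RNA and microRNA rows were left out of that set. The 64 abundant genes with a locus of at least 10 kb lay 0.52 (0.47 to 0.56) above the median gene. Their transcripts may still be short, since a locus includes introns, so they do not decide the question. Other differences in library preparation or duplicate handling, and an effect of the siRNA, were not tested and may each contribute.

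Interferon genes were lower in siLinc-Yy1. The abundance trend does not account for it, as the list stood at -0.22 (-0.30 to -0.10) after its subtraction. The bound of -0.2 set for this test lies inside that interval, but the list lay below all 10000 lists matched on expression. A general fall of inflammatory genes is argued against, because NF-kB and cytokine genes lay 0.17 (0.086 to 0.26) above matched random lists. Transfected RNA can itself induce interferon genes, so the siNC duplex may have induced more of this response than the siLinc-Yy1 duplex, and with 1 library each this and an effect of Linc-Yy1 could not be separated.

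A further hypothesis, that genes within 1 Mb of Yy1 differ from the rest, found no excess in these libraries. The 16 genes past the filter had a median of 0.065 less the trend, at the 91.0th percentile of 11487 runs of as many neighbouring genes.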
